A study of Homo sapiens with 11 samples.

How the data were processed

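Protein binding to DNA was profiled with CUT&RUN, in which an antibody directs a nuclease to cut the DNA around its target inside permeabilised cells and the released fragments are sequenced. All 11 libraries came from HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen. Per the labels, 3 libraries were labelled edit_myc_FLAG, 3 myc_FLAG and 3 endog_myc, and 1 library each was made with mouse IgG and rabbit IgG. Per the labels' protocols the anti-FLAG antibody was raised in mouse and the anti-myc antibody in rabbit, so the mouse IgG library is the species-matched background for FLAG and the rabbit IgG library for endogenous myc. What "edit" stands for is not given in the labels, and the groups are called by their labels throughout.

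The authors deposited 5 lists of peaks, and no read counts or coverage were used here. Each of the edit_myc_FLAG, myc_FLAG and endog_myc groups (the 3 target lists) has 1 list for its 3 libraries, and whether reads or calls were merged is not given in the sources used here. The 2 IgG lists come from 1 library each. Per the submitters' processing notes, Bowtie2 2.4.5, SAMtools 1.15, MACS3 3.0.0b1 and HOMER 4.10 were used with the hg38 build, and the roles, the options and the control library of the peak calls are not given in the sources used here. The deposited lists give for each peak a start and end, the position of its summit as an offset in bases, a caller score, a fold enrichment and a −log10 q, all made by the authors' peak caller. The authors' fold and −log10 q are values of single peaks and were used to describe, rank or filter peaks within one list and to compare its shared with its unshared regions, and their values were not tested between lists. The authors' score was a rescaled −log10 q and was not tested, and a deposited −log10 p was not used. Read depth is unknown from the peak lists, so a longer list can come from deeper sequencing as well as from more binding. As each list merges its replicates, regions or genes were the units of the tests, no p-value measures the spread between replicates, and intervals cover counting error only. Neighbouring regions and genes are not fully independent, which makes the p-values smaller than independent units would give.

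Positions are given on hg38, counted from 1. Tests used chromosomes 1 to 22 and X. Genes came from a RefSeq table for the same assembly that lists the span of each gene but no strand, exons or genome sequence, so 19970 protein-coding genes were tested. The plan, fixed before the data were examined, called for promoters defined by transcription start sites. Without strand, a gene end was used in their place: a region was at a gene end when its summit lay within 1000 bp of either end of a protein-coding gene's span. This can place a region at the 3' end of a gene, and exon, intron and UTR could not be told apart. As a check on the substitution, genes with a divergent transcript named after them were examined, since that transcript marks the start side. The region lay on that side for 43 of 44 such genes in edit_myc_FLAG, 18 of 18 in myc_FLAG and 24 of 24 in endog_myc. The other regions were divided into those inside a gene, those outside genes but within 100000 bp of any annotated gene, and those farther away, called gene-poor. Planned searches for the E-box motif and draws matched on promoter GC content were not run, because no genome sequence was used here.

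A region was shared when it overlapped a region of another list by at least 1 bp. Shared numbers were set against 100000 random placements of the regions on the same chromosome, between its outermost annotated genes or regions, in a one-sided permutation test. Assembly gaps were not excluded. The smallest p these placements can give is 1e-05. Gene-level overlap, location shares and gene lists were tested with two-sided Fisher's exact tests, differences in gene lists between peak lists with exact McNemar tests, and the fold of shared against unshared regions with a two-sided permutation test of medians with 100000 resamples. Benjamini-Hochberg adjustment was applied within each family: 20 ordered pairs of lists, 10 pairs at the gene level, 9 comparisons of the share at gene ends, 120 tests of gene lists and 72 tests of differences in gene lists. Shares carry 95% Wilson intervals, and for a count of 0 the upper limit allows 3 counts.

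The 24 gene lists were fixed before the data were examined. They cover the MAX network, MYC target genes (written from memory of a public list), ribosome biogenesis, cytosolic and mitochondrial ribosomal proteins, translation factors, tRNA synthetases, nucleotide and polyamine synthesis, glycolysis, cell cycle, chaperones, proteasome, histones, circadian genes, lysosomal genes, oxidative phosphorylation, immediate early genes, zinc finger genes and the SNHG snoRNA host genes. Control lists were olfactory receptors and liver, muscle, immune and neuronal genes. The SNHG list was tested among long non-coding genes, without its 2 protein-coding members. The genes named in the text followed a fixed rule. It took the 10 genes with the highest mean rank of fold among genes with a region in all 3 target lists and in no IgG list, the 5 genes with the highest fold in 1 target list that lacked a region in another, up to 4 members of each gene list, and the MAX network in full. Genes named outside this rule are said to be so.

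The gene-poor class, the check of gene sides, the test of how many endogenous regions each FLAG list contained, the non-coding genes, the close-neighbour genes and the chromosome counts were chosen after a first look at the data. The alternatives tried were other overlap rules, other windows around gene ends, a −log10 q of at least 5, lists without regions that overlap IgG, the same number of top regions in each list, placement on gene ends, the −log10 q as the measure, other numbers of top regions, and assignment of a region to its nearest gene alone. Overlap, placement and the gene list test were tested on simulated data first: of 200 shared regions planted between edit_myc_FLAG and endog_myc, 202 overlaps were found, and 201 were found for myc_FLAG and endog_myc. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1 were used.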

Results

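CUT&RUN was run in HEK293T cells against the FLAG tag in cells labelled edit_myc_FLAG and myc_FLAG, against endogenous myc, and with mouse and rabbit IgG as background. MYC is a transcription factor that binds DNA as a dimer with MAX and is known to occupy promoters of genes for growth and metabolism. The edit_myc_FLAG list held 2172 regions, the myc_FLAG list 1290 and the endog_myc list 1359, each made from 3 libraries. The IgG lists, from 1 library each, held 305 regions for mouse and 309 for rabbit. On chromosomes 1 to 22 and X lay 1942, 1073, 1143, 230 and 228 of these. Regions were narrow, with a median width of 254 bp in edit_myc_FLAG, 298 bp in myc_FLAG and 322 bp in endog_myc, and their median fold, as given by the authors, was 5.36, 5.51 and 5.49. A −log10 q of at least 5 was reached by 49.4% of the edit_myc_FLAG regions, 68.4% of the myc_FLAG regions and 67.8% of the endog_myc regions. Read depth is unknown, and nothing in the lists measures the spread between replicates.

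The background comparison asks which regions also appear without a specific antibody. Most of the 100 regions with the highest fold in each target list recurred in the IgG lists, and few of the 100 lay at gene ends. Not every high region recurred: a region of chromosome Y from 11721930 to 11722111 had a fold of 42.0 in edit_myc_FLAG and overlapped no IgG region. Nearly the same interval, from 11721933 to 11722111, was in myc_FLAG with a fold of 35.5. Whether reads map uniquely there was not examined, so this region is no evidence of binding. A region on chromosome 13 from 109424129 to 109424336 was among the 5 highest in all 3 target lists, with a fold of 36.9 in edit_myc_FLAG, and it was the highest in rabbit IgG with a fold of 32.2. A region of chromosome 17 from 25920050 to 25920371 had a fold of 40.8 in edit_myc_FLAG and also overlapped an IgG region. Of the 100 regions with the highest fold, 68 in edit_myc_FLAG, 58 in myc_FLAG and 67 in endog_myc overlapped an IgG region, and only 3, 1 and 4 of them lay at a gene end. The named regions were picked after their values were seen.

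Over the whole lists, 267 of 1942 edit_myc_FLAG regions overlapped either IgG list (13.7%, 95% Wilson interval 12.3 to 15.4). The numbers were 272 of 1073 in myc_FLAG (25.3%, 22.8 to 28.0) and 270 of 1143 in endog_myc (23.6%, 21.3 to 26.2). Against the species-matched mouse IgG, 9.94% of edit_myc_FLAG and 18.7% of myc_FLAG regions overlapped, and against rabbit IgG 18.1% of endog_myc regions. In the other direction, 84.3% of mouse IgG regions recurred in edit_myc_FLAG, and 95.2% of rabbit IgG regions recurred in endog_myc. The mean over random placements was below 1 region in every one of the 20 ordered pairs of lists. In all of them the adjusted p of the permutation test was 1e-05, the smallest the placements can give.

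Over the whole lists, the share of regions near genes was higher in the target lists than in IgG. In edit_myc_FLAG 696 regions lay within 1 kb of a gene end (35.8%, 33.7 to 38.0), against 255 in myc_FLAG (23.8%, 21.3 to 26.4) and 287 in endog_myc (25.1%, 22.7 to 27.7). In mouse IgG the share was 1.304% (0.445 to 3.76) and in rabbit IgG 5.70%. Each target list exceeded each IgG list in Fisher's exact test, with the largest adjusted p at 2.28e-11 for myc_FLAG against rabbit IgG. The target lists are longer, and no comparison with IgG at equal length was run. Of the 100 highest-fold regions, only 3 in edit_myc_FLAG, 1 in myc_FLAG and 4 in endog_myc lay at a gene end. List length may therefore contribute to the difference from IgG. The share in edit_myc_FLAG was 12.1 percentage points above myc_FLAG (exact test, adjusted p = 8.21e-12) and 10.7 points above endog_myc (exact test, adjusted p = 5.89e-10). The shares of myc_FLAG and endog_myc did not differ past the threshold (exact test, adjusted p = 0.489). Without regions that overlap IgG the shares were 40.9%, 30.7% and 31.8%.

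**Figure D1:**
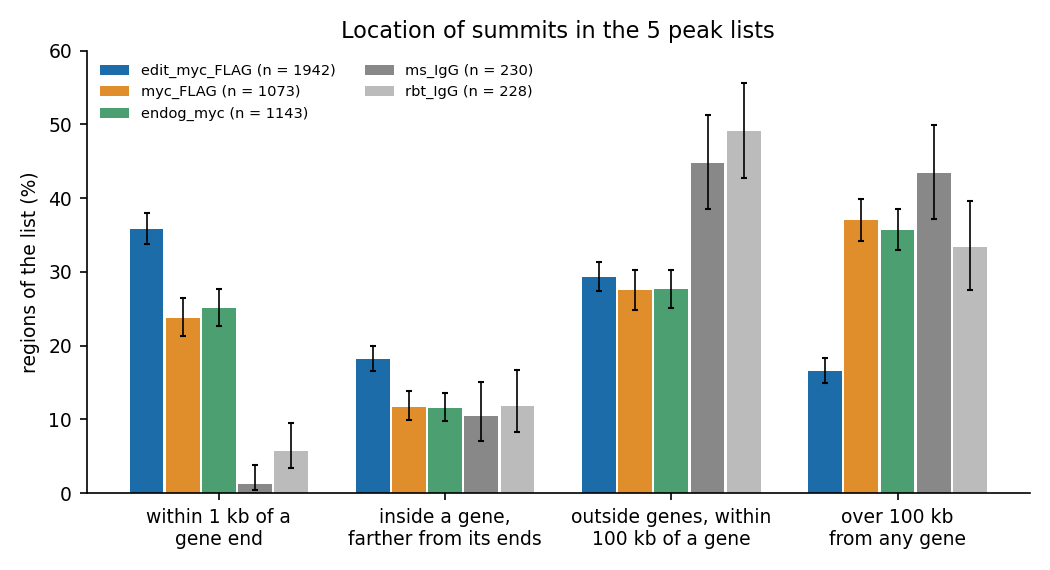
Percentage of the regions of each peak list (bars, with 95% Wilson intervals) by the location of the summit, for the 3 target lists and 2 IgG lists on chromosomes 1 to 22 and X. The edit_myc_FLAG list stands at 35.8% at gene ends, above myc_FLAG at 23.8% and endog_myc at 25.1%, and at 16.6% among gene-poor regions, below their 37.0% and 35.7%.

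The difference was mirrored far from genes. Regions more than 100 kb from any annotated gene made up 16.6% of edit_myc_FLAG (15.0 to 18.3), 37.0% of myc_FLAG (34.2 to 39.9) and 35.7% of endog_myc (33.0 to 38.5). Mouse IgG had 43.5% there and rabbit IgG 33.3%. The edit_myc_FLAG share lay below that of myc_FLAG (exact test, adjusted p = 2.92e-34) and of endog_myc (exact test, adjusted p = 6.32e-32). Without IgG regions, gene-poor regions were still 13.5% of edit_myc_FLAG, 36.2% of myc_FLAG and 34.6% of endog_myc.

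The comparison of the FLAG lists with endogenous myc asks whether regions of the FLAG lists lay where endog_myc regions lay. Most regions of the shorter lists recurred. Of the myc_FLAG regions, 668 overlapped edit_myc_FLAG (62.3%, 59.3 to 65.1) and 656 overlapped endog_myc (61.1%, 58.2 to 64.0). Of the 1143 endog_myc regions, 684 overlapped edit_myc_FLAG (59.8%, 57.0 to 62.6) and 651 overlapped myc_FLAG (57.0%, 54.1 to 59.8), a difference that did not pass the threshold (exact McNemar test, adjusted p = 0.0614). The longer edit_myc_FLAG list shared 676 regions with myc_FLAG (34.8%) and 699 with endog_myc (36.0%). The highest number reached by any of the random placements was 8 regions.

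Part of this sharing was background. Among the 873 endog_myc regions outside IgG, 434 overlapped edit_myc_FLAG (49.7%, 46.4 to 53.0) and 391 overlapped myc_FLAG (44.8%, 41.5 to 48.1), a difference with an adjusted p of 0.0159 in the exact McNemar test. Among the 278 of them at gene ends, 174 overlapped edit_myc_FLAG (62.6%, 56.8 to 68.1) and 127 overlapped myc_FLAG (45.7%, 39.9 to 51.6; exact McNemar test, adjusted p = 1.80e-06). The lists differ in length, and with the same number of highest-fold regions in both FLAG lists the order over all 873 regions turned, to 33.4% in edit_myc_FLAG and 44.8% in myc_FLAG (exact test, p = 7.51e-09). At gene ends the difference shrank to 50.4% against 45.7% under that setting (exact test, p = 0.213).

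Shared regions carried a higher fold than unshared ones within each list. The median was 6.03 for the 842 shared and 5.07 for the 1100 unshared regions of edit_myc_FLAG, 5.85 against 4.87 in myc_FLAG and 5.90 against 4.91 in endog_myc. The permutation test gave 1e-05 in each list, the smallest it can give. Of the 100 highest-fold regions wherever they lay, 88 of edit_myc_FLAG overlapped myc_FLAG and 84 overlapped endog_myc. For myc_FLAG, 79 overlapped edit_myc_FLAG and 86 endog_myc, and for endog_myc 83 overlapped edit_myc_FLAG and 93 myc_FLAG. Among the 100 highest-fold regions at gene ends and outside IgG, 78 of myc_FLAG and 81 of endog_myc overlapped edit_myc_FLAG, whereas 54 of edit_myc_FLAG overlapped myc_FLAG and 54 overlapped endog_myc.

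At the level of genes, 853 protein-coding genes had an edit_myc_FLAG region at an end, 330 a myc_FLAG region and 359 an endog_myc region, of 19970 tested. The mouse IgG list had 4 and the rabbit IgG list 17. A common set of 149 genes was in all 3 target lists, and 11 of them were also in an IgG list. The pair edit_myc_FLAG and myc_FLAG shared 222 genes where independent lists would share 14.1, a ratio of 15.7. The pair edit_myc_FLAG and endog_myc shared 234 where 15.3 would be shared, a ratio of 15.3, and the pair myc_FLAG and endog_myc 175 where 5.93 would be, a ratio of 29.5. The largest adjusted p of these 3 was 1.17e-229 in Fisher's exact test. Rabbit IgG genes recurred too, with 15 of 17 in edit_myc_FLAG, a ratio of 20.7 (exact test, adjusted p = 6.41e-19). Of the same 17 genes, 12 were in myc_FLAG, a ratio of 42.7, and 13 in endog_myc, a ratio of 42.5. A high ratio alone thus does not tell target binding from background. None of the 4 mouse IgG genes was in a target list or in rabbit IgG (exact test, adjusted p = 1 for each pair). In edit_myc_FLAG alone were 546 genes, in myc_FLAG alone 82 and in endog_myc alone 99. Being in 1 list alone is no measured loss in another, as a list ends at its caller's threshold.

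**Figure D2:**
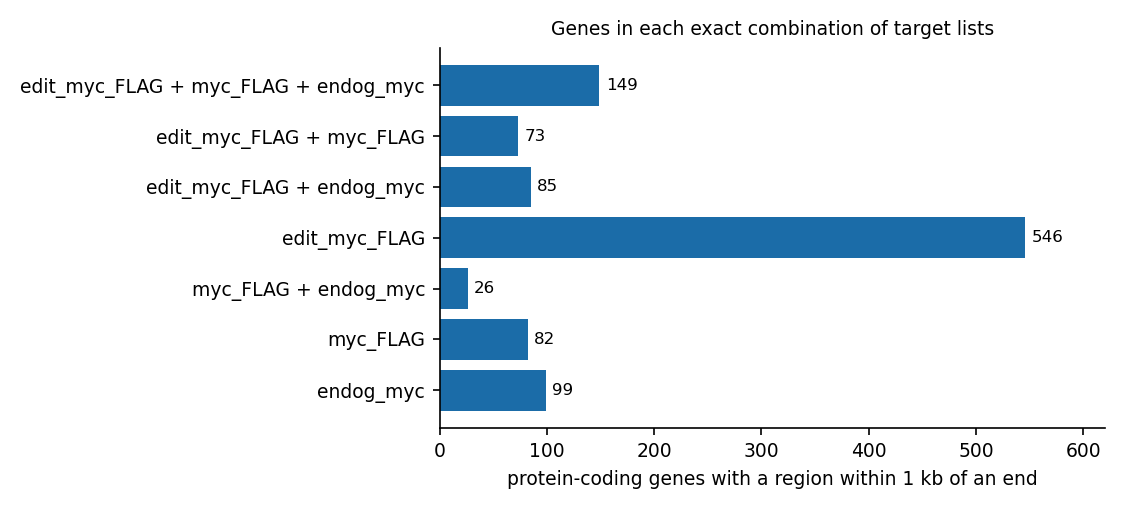
Number of protein-coding genes (bars) with a region within 1 kb of an end in exactly the combination of target lists named on the vertical axis. The 3 lists have 149 genes in common, and 546 genes appear in edit_myc_FLAG alone.

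Among genes in all 3 target lists and in no IgG list, the 10 that ranked highest by fold were LOC124903130, SNRPA, P4HB, SWSAP1, CAMTA1, ADI1, HNRNPC, MYPOP, OSBP and MTRFR. SNRPA encodes a protein of the U1 small nuclear ribonucleoprotein. Its regions lay on chromosome 19 just outside its span (40751203 to 40765389), from 40750635 to 40751108 in edit_myc_FLAG, with folds of 8.55 in edit_myc_FLAG, 9.78 in myc_FLAG and 9.62 in endog_myc, and they were also within 1 kb of ACTMAP. P4HB, a protein disulfide isomerase of the endoplasmic reticulum, had a region on chromosome 17 from 81860637 to 81860897 in edit_myc_FLAG, with folds of 8.66, 9.04 and 10.2 in the same order. CAMTA1, a calmodulin-binding transcription activator, had a region on chromosome 1 from 6784740 to 6785441, and its folds were 10.99, 8.70 and 8.30. HNRNPC, which binds pre-mRNA, had a region on chromosome 14 from 21269477 to 21269680, with folds of 7.20, 9.19 and 8.49. MYPOP, a Myb-related transcription factor, had 7.81, 7.08 and 12.3, and OSBP, an oxysterol-binding protein, had 7.14, 7.14 and 11.1. ADI1, an enzyme of methionine salvage, had 9.18, 8.34 and 8.20. MTRFR, a mitochondrial translation release factor, had 7.47, 7.51 and 8.62. SWSAP1, a factor of homologous recombination, had 8.16, 10.8 and 8.30. The locus LOC124903130 on chromosome 13 had the highest edit_myc_FLAG fold of the group at 13.0, and its summit there lay 704 bp inside its short span.

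The genes with the highest fold in 1 list and no region in another are given with that fold. In edit_myc_FLAG but not in myc_FLAG were AKAP8L, a nuclear A-kinase anchoring protein relative (fold 10.3), ABHD17B, a depalmitoylase (9.85), LSM1, a factor of mRNA decapping (8.74), SH3BGRL2 (8.48) and LOC124905351 (10.02). The gene annotation gave LOC124905351 a span of 2689 to 11139 on chromosome 3. Whether that span refers to the assembled chromosome was not checked, so the link of this region to the gene is uncertain. The edit_myc_FLAG region of AKAP8L lay at the end near 15418988 on chromosome 19, while an endog_myc region (fold 5.38) lay beside the opposite end and was nearer to AKAP8. ABHD17B, LSM1, LOC124905351, UBP1 (10.3) and ATF7-NPFF (8.94) were in edit_myc_FLAG and not in endog_myc, and ATF7-NPFF shares its end with ATF7, a basic leucine zipper factor.

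In myc_FLAG but not edit_myc_FLAG were TOM1, a factor of endosomal sorting (9.98), LIN37, a subunit of the DREAM and MuvB complexes (8.25), ZNF678 (7.75), CHCHD6, a protein of mitochondrial cristae (7.24), and KIAA0319L (7.05). LIN37, CHCHD6, ATF7-NPFF (7.68), DRC3 (9.93) and AARS1, the alanyl-tRNA synthetase (7.90), were in myc_FLAG and not in endog_myc. In endog_myc but not edit_myc_FLAG were RPRD2 (8.76), SPRYD3 (8.72), ZSWIM3 (8.14), GSK3B, a serine/threonine kinase (7.74), and PABPN1, the nuclear poly(A)-binding protein (7.38). SPRYD3, ZSWIM3, H3-3B, a replication-independent histone gene (10.2), TYK2, a Janus kinase (8.72), and MACO1 (8.35) were in endog_myc and not in myc_FLAG. Discordant genes were counted by an exact McNemar test, with 631 in edit_myc_FLAG and not myc_FLAG against 108 the other way (p = 1.09e-90). The test compares lists of different length.

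The fixed gene lists ask whether classes of genes known to respond to myc were bound more often than other genes. Ribosome biogenesis was the list with the lowest unadjusted p among those above other genes in edit_myc_FLAG: 7 of its 61 genes had a region at an end (11.5%, 5.67 to 21.8) against 4.25% of other genes (exact test, p = 0.0149, adjusted p = 0.357), and 0 of 61 did in myc_FLAG and in endog_myc, which allows up to 4.92%. Its members were WDR74, NOP2, UTP18, FBL, NOP56, RRP1B and LTV1. UTP18 had a fold of 6.31, FBL, the nucleolar methyltransferase fibrillarin, 5.30, and RRP1B 4.95. Of these members 4 were the nearest gene to the region. The WDR74 region (5.78) lay 915 bp from its end and 61 bp from STX5, the NOP2 region (4.85) 853 bp from its end and 24 bp from IFFO1, and the FBL region 914 bp from its end and 618 bp from DYRK1B. LTV1, STX5, IFFO1 and DYRK1B were named after their values were seen.

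Of the 59 genes on the MYC target list, 5 had an edit_myc_FLAG region (8.47%, 3.67 to 18.4; exact test, adjusted p = 0.801), 0 a myc_FLAG region, which allows up to 5.08%, and 1 an endog_myc region. The edit_myc_FLAG members were WDR74, NOP2, NOP56, a box C/D ribonucleoprotein component (4.82), RABEPK (4.88) and UNG, the uracil-DNA glycosylase, which was also the endog_myc member and is named outside the rule. The list shares 22 genes with ribosome biogenesis, 3 of them among those bound. In the MAX network, MXD1 (fold 5.97) and MXD3 (4.50), MAX partners that oppose MYC, had an edit_myc_FLAG region. MYC, MAX, MXI1, MXD4, MNT, MGA, MLX, MLXIP, MLXIPL, MYCN and MYCL had none in any list, and no MAX network gene had one in myc_FLAG or endog_myc.

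Other growth and metabolism lists had few members in each target list. Nucleotide and polyamine synthesis had 3 of 34 genes in edit_myc_FLAG and 3 in myc_FLAG (8.82%, 3.05 to 22.96; for myc_FLAG exact test p = 0.0183, adjusted p = 0.367) and 1 in endog_myc. MTHFD1, a folate enzyme (7.20 in edit_myc_FLAG, 5.19 in myc_FLAG), and CTPS1, a CTP synthase (5.91 and 6.48), were in both FLAG lists, RRM2, a ribonucleotide reductase subunit, was in edit_myc_FLAG (5.36) and endog_myc (3.97), and the myc_FLAG region at GART (6.54) was nearer to SON. Chaperones had 3 of 22 genes in edit_myc_FLAG and 2 in each of the others, with the adjusted p at 0.641 or above in exact tests. HSPA1B, an inducible heat shock protein, was in all 3 lists with folds of 4.85, 7.78 and 8.40, HSPA5, the chaperone BiP, was in edit_myc_FLAG (7.17) and myc_FLAG (5.40), HSPA8 was in edit_myc_FLAG (6.15), and the endog_myc region at TCP1 (4.61) was nearer to MRPL18. Oxidative phosphorylation had 5, 4 and 3 of 82 genes, in the order edit_myc_FLAG, myc_FLAG and endog_myc, among them NDUFV3 (6.45 in edit_myc_FLAG), SDHA (6.33), UQCRQ (5.18) and NDUFA11 (5.06). The edit_myc_FLAG regions at SDHA and NDUFA11 were nearer to CCDC127 and VMAC.

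Translation factors had 4 of 38 genes in edit_myc_FLAG (10.5%, 4.17 to 24.1) and 1 in each of myc_FLAG and endog_myc. The initiation factor genes EIF4A1 (6.10) and EIF5 (5.06) and the release factor gene ETF1 (5.36) were in edit_myc_FLAG, and EIF5A was in all 3 target lists with folds of 8.92, 5.92 and 6.35, and also in rabbit IgG with 6.11. Cytosolic ribosomal proteins had 1 of 86 genes in edit_myc_FLAG, RPS14 (4.08), and 0 in the other target lists. Mitochondrial ribosomal proteins had 2, 1 and 3 of 77 genes, with MRPS12 in all 3 lists (5.46, 7.84 and 8.10) where SARS2 was nearer to each region, MRPS9 in edit_myc_FLAG (4.44), and MRPL54 (5.08) and MRPL18 (4.61) in endog_myc. The tRNA synthetases had AARS1 in both FLAG lists, glycolysis had GPI in edit_myc_FLAG (7.52) and endog_myc (7.09), and the proteasome had PSMA5 in myc_FLAG (5.07). The cell cycle list had CDK2 in endog_myc (7.22), nearer to RAB5B. The SNHG host genes had 2 of 32 in edit_myc_FLAG and 1 in each of the others. None of these lists passed the adjusted threshold.

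Of the lists that are not tied to growth, the clock genes PER3 (7.17) and CRY1 (6.86) and the immediate early gene JUN (7.32) had a region in edit_myc_FLAG alone, and KLF6 had one in edit_myc_FLAG (6.52) and endog_myc (6.42). Zinc finger genes had 16, 5 and 10 of 509 genes, led by ZNF77 (8.49 in edit_myc_FLAG, 5.74 in myc_FLAG, 7.65 in endog_myc), ZNF664 (7.09), ZNF8 (6.22) and ZNF576 (6.12). The histone genes H2AC25 and H2BC26, neighbours on chromosome 1, shared 1 region in myc_FLAG (3.87) and 1 in endog_myc (6.68), each counted for both genes. In mouse IgG, 2 of 69 histone genes, H2BC4 and H2AC6 (named outside the rule), had a region, which passed the adjusted threshold (exact test, adjusted p = 0.00422). Mouse IgG had only 3 regions at gene ends for its 4 genes, so some region was counted for several genes. Whether H2BC4 and H2AC6 share a region was not examined, and if they do the test counts it for both.

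Olfactory receptor genes, a control list, were the only fixed list that passed in a target list: 0 of 392 had an edit_myc_FLAG region, which allows up to 0.765%, against 4.36% of other genes (exact test, adjusted p = 9.10e-06). With regions of a −log10 q of at least 5 alone, this call was lost (exact test, adjusted p = 0.480). They also had 0 in myc_FLAG (exact test, adjusted p = 0.0671) and in endog_myc (exact test, adjusted p = 0.0621). Liver, muscle, immune, neuronal and lysosomal genes had 0 in each target list, on lists of 20 to 26 genes that allow up to 15.0%. In all, 2 of the 120 exact tests passed the adjusted threshold and 8 had an unadjusted p under 0.05. Of the 72 exact McNemar tests between peak lists 0 passed and 3 had an unadjusted p under 0.05, the lowest for zinc finger genes with 12 in edit_myc_FLAG and not myc_FLAG against 1 the other way (exact test, p = 0.00342, adjusted p = 0.246).

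**Figure D3:**
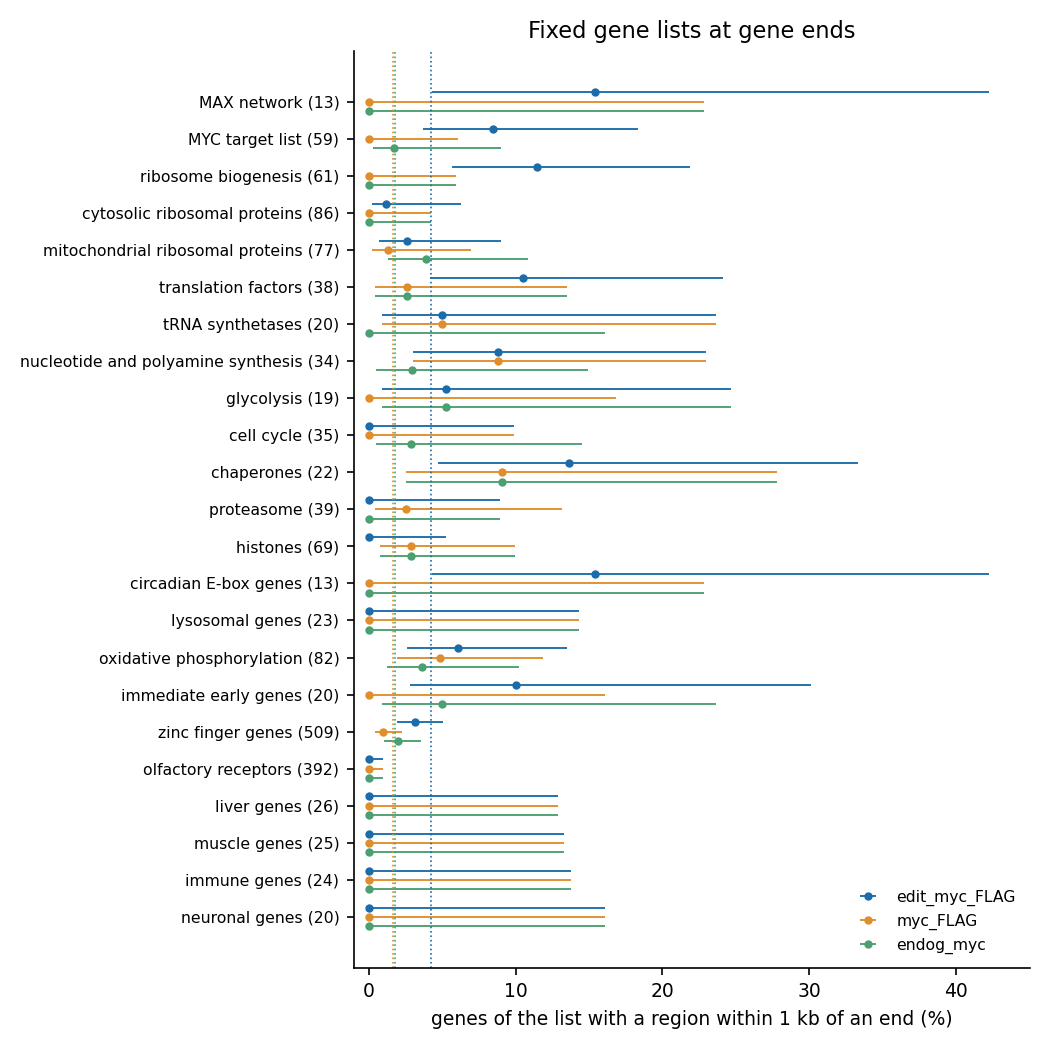
Percentage of the genes of each fixed list with a region within 1 kb of an end (points, with 95% Wilson intervals as lines; list sizes in brackets), for the 3 target lists, with dotted lines at the share among all 19970 genes. SNHG host genes are not drawn, and the intervals of most lists reach across the dotted line of their peak list, with olfactory receptors at 0% below it.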

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

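The tests of list length, of IgG regions and of depth, and the test at matched fold, were chosen after the results were seen, as were the gene-poor class and the count of endogenous regions in the FLAG lists. The tests of IgG overlap at fold 8 or more and of gene density were set before their results were seen, and the count for gene density was limited to regions at gene ends afterwards.

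A difference between groups drew attention to the location of the edit_myc_FLAG regions. Their share at gene ends was 12.1 percentage points above myc_FLAG and 10.7 points above endog_myc, and their share in gene-poor sequence differed by -20.4 points and -19.1 points. More weak regions in a longer list may account for part of the difference at gene ends. At a −log10 q of at least 5 the edit_myc_FLAG share fell from 35.8% to 26.5%, and the shares of the other lists fell too. The lead was then 9.81 points over myc_FLAG (exact test, adjusted p = 8.12e-06) and 6.50 points over endog_myc (exact test, adjusted p = 0.00341). With the same number of highest-fold regions in each list and without IgG regions, edit_myc_FLAG was still at least 13.1 points above each of the others (exact test, adjusted p = 1.85e-07 for endog_myc). The lead under both settings argues against weak regions as the whole explanation. Dilution of the shorter lists by background stays open. Without IgG regions the smaller of the differences at gene ends was 9.05 points (exact test, adjusted p = 1.12e-05). Removal takes out only the background that the short IgG lists caught. After it, gene-poor regions were still 36.2% of myc_FLAG and 34.6% of endog_myc, against 13.5% of edit_myc_FLAG. In the IgG lists they were 43.5% for mouse and 33.3% for rabbit. Depth may contribute and cannot be told apart from the groups, since the files gave the read depth of 0 libraries; a difference in binding between the cells labelled edit_myc_FLAG and myc_FLAG stays open too and is untested.

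The sharing of gene ends among the 3 target lists has a technical explanation in untargeted cutting at open promoters, which would put the same ends into IgG. Among regions of fold 8 or more, 5 of 37 at gene ends overlapped IgG in edit_myc_FLAG against 107 of 178 elsewhere, with 6 of 22 against 103 of 188 in myc_FLAG and 5 of 30 against 99 of 164 in endog_myc, and the largest exact p was 0.0224. That test leaned on fold, since the median fold was 8.92 at gene ends and 10.99 elsewhere in edit_myc_FLAG. At fold 8 to 10 the difference held in edit_myc_FLAG (exact p = 0.000402) and endog_myc (exact p = 0.00135) and not in myc_FLAG, with 5 of 19 against 37 of 74 (exact p = 0.0753), so untargeted cutting may still account for part of the sharing, and each IgG list rests on 1 library. Gene density is argued against: when only the regions at gene ends were placed on random gene ends, at most 14 were shared, against 127 or more observed with or without IgG regions, and common binding by myc stays open as a hypothesis.

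A difference between groups also appeared in how many endogenous regions at gene ends each FLAG list held, 16.9 percentage points more in edit_myc_FLAG than in myc_FLAG among the 278 outside IgG. With the same number of highest-fold regions in both FLAG lists it was 4.68 points (exact test, p = 0.213), so list length may account for much of it.

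Signal in data outside the comparisons appeared on sequences other than chromosomes 1 to 22 and X. There, 145 of 230 edit_myc_FLAG regions, 129 of 217 myc_FLAG regions and 126 of 216 endog_myc regions overlapped no IgG region. Of the 230, 217 and 216 regions, 33, 39 and 32 lay on chromosome Y. Whether reads map uniquely to these sequences was not examined, so no binding there can be read from the counts.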

How the results depend on the processing

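The lists with the same number of top regions for gene ends, the assignment to the nearest gene and the alternatives for endogenous regions in the FLAG lists were chosen after seeing the data. The 36 recomputed overlaps between target lists (24.8% to 68.9% of regions), the 18 with IgG, the 12 gene-level overlaps, the 15 differences in the share at gene ends and the 9 differences in fold kept their direction and their side of the threshold. The share of endogenous regions outside IgG held by edit_myc_FLAG minus that of myc_FLAG reversed to -11.3 points with the same number of top regions in both FLAG lists, the shortening of the longer list being part of that setting. It lost the threshold at a −log10 q of at least 5 (0 points), with 50% of both regions overlapping (2.29 points) and with summits within 200 bp (2.63 points), and at gene ends with the same number of top regions (4.68 points); the cause was not tested. Lists bound less often than other genes went from 1 to 0 in edit_myc_FLAG at the stricter q, where fewer regions were left, and from 0 to 1 in myc_FLAG and from 0 to 1 in endog_myc with the 2500 bp window, each time olfactory receptors. The share of top regions found in another list rose when they were ranked by −log10 q, to 99.0% of edit_myc_FLAG in myc_FLAG and 98.0% in endog_myc, 98.0% of myc_FLAG in each of the others, and 100% of endog_myc in each. With the top 50 regions it was 92.0% and 94.0% for myc_FLAG in edit_myc_FLAG and endog_myc, and 90.0% and 100% for endog_myc in edit_myc_FLAG and myc_FLAG, and with the top 200 it was 84.5% for endog_myc in myc_FLAG; the cause was not tested.

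No paired analysis was possible because each target list merges its 3 replicates, and for the same reason no replicate was left out. The E-box share and the comparisons matched on promoter GC content were not run. List length limits the gene lists: for the MYC target list, a bound share 3 times that of other genes would be called in 79.8% of 2000 simulated lists for edit_myc_FLAG (unadjusted exact test), 32.6% for myc_FLAG and 39.5% for endog_myc. The bound set before that result was 80%, so at the unadjusted threshold whether the lists were too short could not be decided for edit_myc_FLAG. The gene list calls used the stricter adjusted p, for which the share called can be no higher and was not simulated. The lack of a call for the MYC target list is thus no evidence against a share 3 times that of other genes.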

Other observations

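The tests of chromosomes and of ribosomal RNA genes were chosen after seeing the data; the test of close neighbours by nearest gene was set before its result.

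Genes on chromosome 19 were the most frequent among those with a target region at an end and outside IgG, counted for the nearest gene. They made up 91 of 682 genes in edit_myc_FLAG (13.3%), 59 of 246 in myc_FLAG (24.0%) and 59 of 278 in endog_myc (21.2%), against 7.27% of all protein-coding genes. The exact tests gave adjusted p-values of 4.21e-07, 1.01e-14 and 1.79e-12, and 7 of 69 tests over chromosomes and lists passed. Of the 149 genes in all 3 target lists, 50 lay on chromosome 19. In edit_myc_FLAG, chromosome 21 was also above other chromosomes, with 8.79% of its genes against 3.35% elsewhere (exact test, adjusted p = 0.00133), and chromosome 4 below, with 1.3004% against 3.50% (exact test, adjusted p = 0.00483). The other 2 tests that passed were chromosome 17 in myc_FLAG, with 26 of 246 genes (10.6%) against 5.85% of all (exact test, adjusted p = 0.0418), and chromosome 3 in endog_myc, with 5 of 278 (1.80%) against 5.34% (exact test, adjusted p = 0.0441). Copy number and GC content along chromosomes were not used here.

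Genes with the end of another protein-coding gene within 1 kb of their own, 28.6% of all, made up 46.3% of the 853 genes in edit_myc_FLAG, 53.6% of the 330 in myc_FLAG and 49.0% of the 359 in endog_myc. A candidate explanation is that 1 region counts for both neighbours. Counted for its nearest gene alone, such genes still held 34.2%, 40.4% and 36.9%, above other genes in each list (largest exact p = 0.00240), so double counting does not account for all of the excess; no biological explanation was tested.

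Ribosomal RNA genes overlapped 7 regions in edit_myc_FLAG, 3 in myc_FLAG, 4 in endog_myc and 0 in each IgG list, which allows up to 1.304% and 1.316% of the IgG regions. The shares of the target lists, 0.360%, 0.280% and 0.350% in the same order, lay below those limits, so these counts show no difference from IgG. In edit_myc_FLAG they included the 5S gene RNA5S17 on chromosome 1 (fold 3.39, from 228645979 to 228646527), which also had a myc_FLAG region (2.95), and copies of the 45S unit on chromosome 21 such as RNA45SN2 (3.04). No target region overlapped any of the 443 tRNA genes or 1196 snoRNA genes, which allows up to 0.154% of the edit_myc_FLAG regions. Repeated copies of these genes can share reads, and these genes were named after their values were seen.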
